A study of Gallus gallus with 2 samples.

How the data were processed

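Total RNA (100 ng) from pooled germinal discs was labelled by 3' in vitro transcription and hybridised to the Affymetrix Chicken Genome Array, a 1-colour array, with 1 array for the control pool and 1 for the Bx pool, per the labels' protocols. The table analysed holds 1 linear signal intensity per probe set and array, as deposited by the authors, who made it with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and the probe set definition are not given in the sources used here, and probe-level files and detection calls were not used here. MAS5 subtracts a mismatch-based background and scales each array. In the deposited intensity values the mean without the lowest and highest 2% was 500.1 on both arrays, so the arrays had been brought to 1 common level. A change in total mRNA content would therefore not show in the gene ratios. RNA of the 3 birds of a group was mixed before hybridisation, so differences between birds were not measured.

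Signals were kept as the authors scaled them and taken to log2 with no pseudocount. The 96 control probe sets (IDs starting AFFX) were left out of gene results. The 746 probe sets whose IDs carry neither the chicken nor the control prefix, called non-chicken here, set the background floor as their 95th percentile on each array, a signal of 42.6 on the control and 36.4 on the Bx array. A value under the floor was treated as having only a bound. The number of arrays limits the precision: with 1 per group no test across samples was possible and none was made.

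Probe sets were named from GEO's platform annotation, which can be old, with gene IDs looked up in the RefSeq table of assembly GRCg7b. Of 37693 chicken probe sets, 27166 had 1 gene symbol, 177 had several and 10350 had none. Of those with 1 symbol 98.8% had a gene ID in the RefSeq table, which gave the same symbols. No coordinates are given, because the array was not designed on that build. Of 13008 genes, 10168 were above the floor on both arrays. A gene's value is that of its probe set with the highest mean log2 signal. Other probe sets of the gene were used to measure how far probe sets disagree, as the SD of the log2 ratio between them. Probe sets of one gene can share sequence, and an SD between them covers measurement error on these arrays, not variation between birds.

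The results reported are the log2 ratio of Bx over control, the counts of genes past 2-fold, and the median ratio of 26 gene lists (778 members, 617 matched to a symbol on the array). Each list with at least 5 measured members was ranked among 10000 random lists of as many genes, drawn from the same 20 bins of mean log2 signal. A percentile describes these 2 arrays only, and lists that share genes are not independent. The lists, the floor, the thresholds and the alternatives were fixed before the data were examined, except the limit of 5 members to rank a list, the matching of list members by symbol alone, under the name or names the list gave (other synonyms were dropped, after the percentiles had been seen once with them, because they hit other genes of the same family), the stricter count of genes with at least 2 probe sets all past 1.5-fold, the spread against which a value was said to move between settings (the SD between probe sets for a gene, the SD of random medians for a list), the choice of lists followed through all settings, and the tests named in the closing section as chosen later. Genes named in the text are the 12 highest and 12 lowest ratios among genes with a proper symbol whose probe sets above the floor all went the same way, the 5 largest bounds on each side among genes under the floor on 1 array, up to 4 members of each list with the largest absolute ratio, every measured member of the Fc-binding and yolk uptake lists, and 14 oocyte, granulosa, yolk uptake and immunoglobulin genes. Bright genes and other list members were added after their values were seen.

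Alternatives were median centring, quantile normalization, loess of the ratio on brightness (lowess fraction 0.3), no floor, a stricter floor at the 75th percentile of each array's chicken probe sets (484 and 498), a pseudocount of 16, the mean over a gene's probe sets, leaving out _x_at and _s_at probe sets, leaving out list members whose probe sets disagree, and thresholds of 1.5-fold and 3-fold. The analysis was tested on simulated data made from these arrays with normal noise that depended on brightness. The SD of the noise was that of the observed log2 ratios at the same brightness, which include any real difference. The rate below for unchanged genes therefore follows from the observed spread and is no independent error rate. For the comparison of Bx with control, with 10526 genes run, genes raised by 1 log2 unit had a mean estimate of 0.992. They were past 2-fold in 56% of cases, genes lowered by 1 log2 unit in 43.75%, and unchanged genes in 0.725%. Genes raised or lowered by 2 log2 units were past 2-fold in 100%. These rates leave out genes that fell under the floor: from sets of equal size, 50 genes raised and 38 lowered by 2 log2 units were measured. Of 100 simulated unchanged lists, 6 fell outside the central 95% of random lists. These lists were drawn at random and the noise was independent between probe sets, so real lists whose genes vary together are not covered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.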

Results

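Gene expression was measured in the germinal disc region of maturing chicken oocytes, the small area of the yolk surface that holds the oocyte nucleus, from laying hens whose bursa of Fabricius had been removed before hatching (Bx) and from control hens. The bursa is the organ in which birds make B cells, and the series describes the Bx hens as deficient in IgY, the avian counterpart of IgG that is carried from blood into the yolk. The series used the arrays as a screen for genes raised in oocytes of IgY-deficient birds. The bursa was removed on day 17 to 18 of incubation, and discs were taken at 25 weeks of age from the yellow follicles ranked F5 to F7. Each group was 1 pool of 9 germinal discs from 3 birds, hybridised to 1 Affymetrix Chicken Genome Array. There were therefore 2 arrays and no replicate of either group. No p-value is given for any difference, and variation between birds or pools was not measured. Of the 37693 chicken probe sets, 65.4% were above the background floor on the control array and 68.3% on the Bx array.

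The 2 pools had nearly the same expression profile. Across the 22948 chicken probe sets above the floor on both arrays, log2 signals had a Pearson r of 0.985 and a Spearman rho of 0.978, taken across probe sets, which are not independent replicates. Of the 10168 named genes above the floor on both arrays, 9381 (92.3%) differed by less than 1.5-fold. ZP3, a protein of the inner perivitelline layer around the egg, had a signal of 36001 in the control pool and 35348 in the Bx pool. The error of a ratio depended on brightness. The SD of the log2 ratio over genes was 0.49, 0.31, 0.21 and 0.15 in 4 equal groups of genes from the dimmest to the brightest. These SDs include any real difference. The SD between probe sets of the same gene was 0.45, 0.38, 0.31 and 0.26 in the same order. Genes were grouped here by the brightness of their brightest probe set. In all but the dimmest group this exceeded the SD over genes, so there it is wider than the error of a gene's value. Over 4870 genes with at least 2 probe sets above the floor, the log2 ratios of the brightest and the next probe set had a rho of 0.20 across genes, against at most 0.034 in 100 shuffles of the pairs, and 57.9% of these pairs went the same way. Spiked transcripts added at hybridisation had a median log2 ratio of -0.05 ± 0.07 (SD, 27 probe sets) between the Bx and control arrays. The poly-A spikes were lower on the Bx array, at -0.22 ± 0.19 (median, SD, 36 probe sets), and 34 of the 36 were lower. Whether this reflects the mRNA content of the pools or the handling of the spikes cannot be told apart here. The ratio of 3' to 5' signal, a sign of RNA integrity, was 1.48 in the control and 1.5 in the Bx pool for actin, 1.07 and 1.05 for GAPDH, and 1.91 and 1.64 for EF1A.

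The comparison of the Bx pool with the control pool gave few differences of 2-fold or more, and these were mostly in dim genes. In the Bx pool 65 genes were at least 2-fold higher and 43 at least 2-fold lower, together 1.06% of the genes measured. Those higher in the Bx pool included UGCG, the glucosylceramide synthase (signal 44.4 in the control and 191 in the Bx pool, 4.30-fold), and ELN, which encodes elastin (87.1 and 332, 3.81-fold). The 2 probe sets of UGCG were both higher but far apart, with a mean log2 ratio of 1.21 ± 1.26 (SD). DPYSL3 was 3.21-fold higher, FAM129A 3.18-fold and AQP2, a water channel, 3.14-fold. NAV3 was 2.92-fold higher, CBLB, a ubiquitin ligase, 2.83-fold (mean log2 ratio 0.86 ± 0.91 over 2 probe sets), TRIM27.2 2.79-fold, GMEB2 2.77-fold, FGF13 2.73-fold, ERCC6L 2.67-fold and IGFN1 2.60-fold. On the lower side, EGFL6 went from 469 in the control to 106 in the Bx pool (4.43-fold lower) and EMID1 from 190 to 48.5 (3.91-fold lower). SPSB1 was 3.56-fold lower, CYP26B1, an enzyme that degrades retinoic acid, 3.12-fold, and TOP1, which encodes DNA topoisomerase I, 3.12-fold. CYP2W1 was 2.85-fold lower, RAP1GAP1 2.79-fold, the tight junction gene TJP3 2.63-fold, the Src-family kinase gene FGR 2.60-fold, TM2D2 2.60-fold, GALNT5, which starts mucin-type O-glycans, 2.46-fold, and ZFPM1, a cofactor of GATA factors, 2.46-fold.

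Every one of the 65 higher genes and 41 of the 43 lower genes lay in the dimmer 2 of the 4 brightness groups. Another probe set above the floor was available for 16 of the higher genes, and all probe sets went the same way in 8. This held for 5 of 9 lower genes. ACSL6 (5.32-fold higher) and SYDE2 (6.26-fold lower) had the largest ratios on each side, but their other probe set went the opposite way. FAM129A and GALNT5 were the genes named above with at least 2 probe sets that were all past 1.5-fold, with mean log2 ratios of 1.33 ± 0.49 and -0.96 ± 0.48 (SD, 2 probe sets each). The balance of directions was not settled: 60.2% of the genes past 2-fold were higher in the Bx pool (Wilson 95% interval 50.8 to 68.9, covering counting error only), but with the arrays centred on their medians the counts were 51 higher and 66 lower, and 43.6% were higher. That centring put the median log2 ratio over genes at -0.04, which itself tilts the counts to the lower side.

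**Figure D1:**
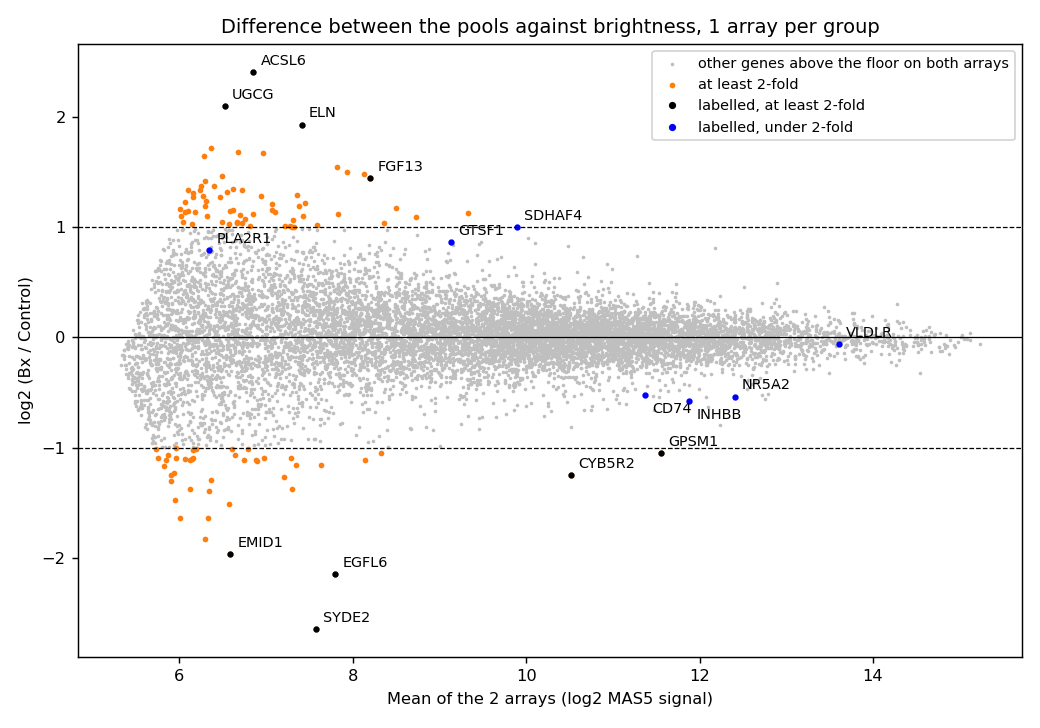
Log2 ratio of the Bx over the control signal (vertical axis) against the mean log2 MAS5 signal of the 2 arrays (horizontal axis) for the 10168 genes above the floor on both arrays, 1 point per gene, with orange points for genes past 2-fold, labelled genes in black past 2-fold and in blue under it, and dashed lines at 2-fold. The spread narrows with brightness, from an SD of 0.49 in the dimmest group to 0.15 in the brightest, and CYB5R2 and GPSM1 stand apart among the bright genes.

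Among the 5601 bright genes, those above the 75th percentile of chicken probe sets on both arrays, 2 were at least 2-fold lower in the Bx pool and 0 were at least 2-fold higher. CYB5R2, a cytochrome b5 reductase, went from 2258 to 948 (2.38-fold lower, 1 probe set). GPSM1, a modulator of G-protein signalling, went from 4331 to 2090 on its brightest probe set, and its 3 probe sets had a mean log2 ratio of -0.51 ± 0.47 (SD). At 1.5-fold, 21 bright genes were higher and 29 lower. The bright genes named here were chosen after their values were seen. SDHAF4, an assembly factor of succinate dehydrogenase, went from 673 to 1343, and its 2 probe sets gave a mean log2 ratio of 0.94 ± 0.08. LARP4B, an RNA-binding protein gene, had a mean log2 ratio of 0.96 ± 0.22 over 3 probe sets, and the nuclear receptor gene NR2C1 0.55 ± 0.33 over 3. CEBPB, a transcription factor gene, was 1.80-fold higher on its 1 probe set. P2RY6, a receptor for UDP, had a mean log2 ratio of -0.81 ± 0.14 over 2 probe sets, FOXP1 -0.56 ± 0.23 over 2, and PLCG1, a phospholipase C gene, -0.46 ± 0.18 over 3.

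A further 128 genes were above the floor by at least 1 log2 unit in one pool and under it in the other, 95 with the higher signal in the Bx pool and 33 with the higher signal in the control. Their fold is a lower bound against the floor. The floor was lower on the Bx array (36.4) than on the control (42.6), and each array's margin was taken from its own floor. A smaller signal therefore sufficed to count a gene as higher in the Bx pool than to count one as lower. The excess of 95 over 33 is for this reason not read as more genes raised in the Bx pool. How much of it came from the unequal floors was not tested. On the higher side, QSOX1, a sulfhydryl oxidase gene, was at least 3.31-fold higher in the Bx pool, RAB7L1 at least 3.07-fold, CLIC5 at least 2.92-fold on its brightest probe set, ACAA1 at least 2.88-fold and NTNG2 at least 2.78-fold. On the lower side, TECRL was at least 3.89-fold lower, PLCD4 at least 3.81-fold, NIPAL4 at least 3.76-fold, LGALSL2 at least 3.49-fold and PFKFB2 at least 3.10-fold. A further CLIC5 probe set, above the floor on both arrays, had a log2 ratio of 0.09. The signals of these 10 genes on their brightest probe sets were under 142 on both arrays, close to the floor of 42.6 on the control and 36.4 on the Bx array.

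The lists of Fc-binding and immunoglobulin transport genes and of yolk uptake receptors and their partners were closest to the purpose of the screen. Whether any of these genes carries IgY into the oocyte was not tested here. Of the 16 genes of these lists above the floor on both arrays, 1 was at least 1.5-fold higher in the Bx pool and 0 were at least 1.5-fold lower. The one was PLA2R1, the gene annotated on the array for the phospholipase A2 receptor, whose chicken form FcRY binds IgY. Its signal was 61.9 in the control and 107 in the Bx pool (1.73-fold, log2 ratio 0.79), on the only 1 of its 3 probe sets above the floor, in the dimmest group of genes, where the SD over genes was 0.49. Of the 400 genes nearest to it in mean signal, 57 differed by at least as much. LY75, a mannose-receptor family member, had a log2 ratio of 0.56 on its brightest probe set and a mean of 0.15 ± 0.58 (SD) over 2 probe sets that went opposite ways. LGALS3 had a log2 ratio of 0.44 and B2M, the light chain of MHC class I, 0.14 on probe sets that went both ways. FCER1G, the Fc receptor gamma chain, had -0.45. VLDLR, the oocyte receptor for very low density lipoprotein and vitellogenin, was among the brightest, with 12750 in the control and 12216 in the Bx pool (log2 ratio -0.06). Its chaperone LRPAP1 had a log2 ratio of 0.23, the adaptor DAB2 0.04, SCARB1, a lipoprotein receptor, 0.17, LRP5 -0.05, LRP6 -0.21 and LRP4 0.0018 on probe sets that went both ways. SORL1 had -0.53 on its brightest probe set, with a mean of -0.78 ± 0.35 (SD) over 2. STRA6, the receptor for retinol-binding protein, had -0.40, TFRC, the transferrin receptor, -0.38 and CUBN, cubilin, -0.29 on probe sets that went both ways. AMN, the partner of cubilin, was under the floor in the control pool (signal 32.6) and 116 in the Bx pool, at least 2.73-fold higher. LRP8, LRP2, LRP1B, LRP1, MRC1, MRC2, PIGR and STAB1 were not above the floor on both arrays.

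**Figure D2:**
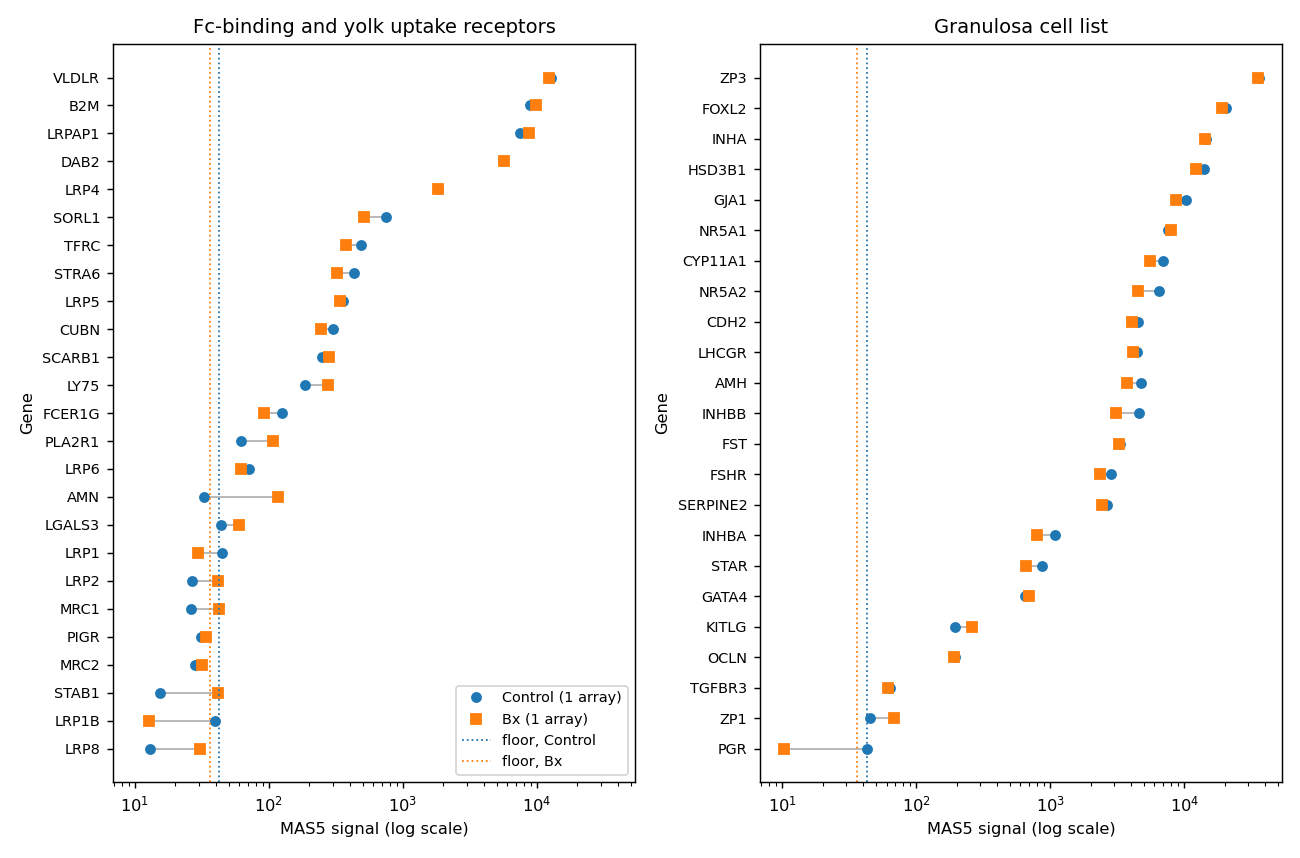
MAS5 signal (log scale) of Fc-binding and yolk uptake receptor genes and their partners (left) and of the granulosa cell list (right), 1 row per gene, with circles for the control array, squares for the Bx array and dotted lines at each array's floor. VLDLR lies at 12750 and 12216, PLA2R1 near the floor at 61.9 and 107, and 18 of the 22 measured granulosa genes have the lower signal in the Bx pool.

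The yolk uptake receptors had a median log2 ratio of -0.06 over 11 measured members, at the 13.9th percentile of 10000 random gene lists of the same size and brightness. Without _x_at and _s_at probe sets the median was -0.13, at the 2.61st percentile, and with the mean over probe sets it was -0.09, at the 5.96th. The Fc-binding and immunoglobulin transport list had a median of 0.44 over 5 measured members, at the 98.3rd percentile. That median was the value of LGALS3 alone, with signals of 43.9 in the control and 59.5 in the Bx pool. The control signal was barely above that array's floor, so the rank of this list rests on a gene close to the background. With the mean over each gene's probe sets the median of the Fc-binding list was 0.15, at the 83.6th percentile. The clathrin endocytosis list had a median of -0.01 over 29 members, with 0 members at least 1.5-fold higher and 1 lower, DNAJC6, an auxilin that uncoats clathrin vesicles (-0.75). GAK, the other auxilin gene, had -0.44 on its brightest probe set, but its probe sets did not go the same way. The adaptor kinase gene AAK1 had -0.42 and EPS15L1 0.34. The endosome sorting and recycling list had a median of -0.0043 over 36 members, none of them past 1.5-fold. VPS4A, an ATPase of the ESCRT pathway, had 0.47, HGS 0.38, RAB11B 0.35 and STAM2 -0.29. The lysosome and yolk proteolysis list had a median of -0.00076 over 29 members, none past 1.5-fold, and its mean was 0.03, while that of the endosome list was 0.02. LAMP3 was at 0.45, HEXA at 0.35 and LAMP1 at 0.24. LIPA, at 0.23, had probe sets that went both ways. The caveolae and macropinocytosis list had a median of 0.04 over 11 members, none past 1.5-fold, with PACSIN3 at 0.40, PRKCDBP at 0.29, RAB34 at 0.24 and FLOT2 at -0.19, on probe sets that went both ways.

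Granulosa cell genes were lower in the Bx pool as a list. These cells surround the oocyte, and 18 of the 22 measured members of the list were bright in both pools. Of 22 measured members, 18 had the lower signal in the Bx pool, and the median log2 ratio was -0.12, at the 0.17th percentile of random lists. Among the bright members the largest differences were in INHBB, the inhibin/activin beta B chain (4604 and 3083, mean log2 ratio -0.65 ± 0.10 (SD) over 2 probe sets), NR5A2, a nuclear receptor gene (6526 and 4496, -0.66 ± 0.18 over 2) and INHBA, the beta A chain (1084 and 794, -0.52 ± 0.09 over 2). STAR, which brings cholesterol into mitochondria for steroid synthesis, was 1.31-fold lower, CYP11A1, the side-chain cleavage enzyme, 1.27-fold lower, and FSHR, the follicle-stimulating hormone receptor, 1.21-fold lower, each on its brightest probe set. INHA, the inhibin alpha chain, had a log2 ratio of -0.02, FST, follistatin, -0.01, NR5A1 0.09 and ZP3 -0.03. KITLG had 0.41, and ZP1 had 0.61, at signals of 44.8 and 68.2. On their brightest probe sets 0 members were past 1.5-fold lower, while the means over probe sets of INHBB and NR5A2 were. Without probe sets that can match several transcripts (_x_at and _s_at), the median was -0.08, at the 4.27th percentile. Beside it, the medians of the lists of other cell types were 0.12 for oocyte and germ cell genes, 0.27 for endothelial cells, 0.18 for leukocytes and thrombocytes, 0.0094 for erythrocytes and -0.01 for theca, fibroblast and smooth muscle cells.

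Oocyte and germ cell genes went both ways. Of 28 measured members, 3 were at least 1.5-fold higher and 4 at least 1.5-fold lower, with a median log2 ratio of 0.12, at the 92.2nd percentile. GTSF1, a piRNA pathway gene, went from 416 to 757 (1.82-fold higher), DDX4, the germ cell helicase Vasa, from 43.6 to 70.6 (1.62-fold), while DDX25 was 1.70-fold lower and MARF1 1.65-fold lower on a brightest probe set that its others did not follow. DAZL, a germ cell RNA-binding protein gene, had a log2 ratio of 0.14, BMP15 0.06 and GDF9 0.46, the last 2 at signals under 95. The oocyte maturation kinases and cyclins had a median of 0.08 over 18 members, at the 97.4th percentile, just inside the central 95%. It was outside after quantile normalization (98.9th percentile), loess (98.7th), with the stricter floor (98.0th) and without _x_at and _s_at probe sets (98.6th), and with the mean over probe sets its median was 0.02, at the 55.3rd percentile. CCNE2, cyclin E2, was 1.57-fold higher, and CDC25A had a log2 ratio of 0.24, PDE3A 0.25, on probe sets that went both ways, and SMC2 -0.28.

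Markers of other cell types were mostly dim or under the floor. The theca, fibroblast and smooth muscle list had a median log2 ratio of -0.01 over 13 members at the 31.1st percentile, with PDGFRA at -0.96, CYP17A1, the androgen-forming enzyme of the theca, at 0.90, PTCH1 at 0.55 and TAGLN at -0.45. The endothelial list had a median of 0.27 over 11 members, at the 97.2nd percentile (97.51st, just outside, after quantile normalization, 98.0th after loess and 45.8th with no floor), with ENG and ERG at 0.56, ESAM at 0.53 and CDH5 at -0.52. The leukocyte and thrombocyte list had a median of 0.18 over 15 members, at the 95.1st percentile, while 21 members on the array were not above the floor in both pools. CD74, the MHC class II invariant chain, was its brightest moving member (3182 and 2212, 1.44-fold lower on the brightest probe set), and its 3 probe sets went the same way. TLR4 had -0.94, C1QC 0.74 and CXCR4 0.43. The erythrocyte list had a median of 0.0094 and a mean of -0.06 over 11 members at the 55.9th percentile, with HBZ at -0.75, HBE at -0.56, HBA1 at 0.36 and SPTB at 0.21. For B cells and immunoglobulin, 8 of 16 genes on the array were measured in both pools, with a median of -0.0014 at the 51.7th percentile (-0.16 with the mean over probe sets, at the 13.7th). PAX5, a B cell transcription factor gene, was 1.79-fold lower, IKZF3 had -0.52, BTK 0.36, and IGLL1, the immunoglobulin light chain, -0.49 at signals of 53.4 and 38.0, on the only 1 of its 8 probe sets above the floor on both arrays. A further probe set of IGLL1 was above the floor in the Bx pool alone (33.4 and 40.4). Of the members above the floor in 1 pool, TNFRSF13B, a receptor gene of B cells, was at least 2.40-fold lower in the Bx pool (87.2 and under the floor), and POU2AF1 (52.7) and CD79B (55.3) were above the floor in the control pool alone. JCHAIN (37.9) and EBF1 (43.0) were above it in the Bx pool alone.

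Of the 25 lists with at least 5 measured members, 6 had medians outside the central 95% of random lists. By chance 1.25 are expected if the genes of a list vary independently. Genes of 1 list can vary together, so the excess was not read as more than chance. Of the 6 lists, those not yet described were lists of basic cell functions. The unfolded protein response list had a median log2 ratio of -0.11 over 20 members, 18 of them below 0, at the 0.25th percentile. EDEM1, which marks misfolded proteins for degradation, was 1.47-fold lower and SEL1L, of the same pathway, 1.33-fold lower on their brightest probe sets, which their other probe sets did not all follow. DNAJB11 had -0.24 and ATF4 -0.17, and 0 members were past 1.5-fold. The cholesterol synthesis list had a median of -0.09 over 18 members, at the 2.0th percentile. FDPS, a prenyl diphosphate synthase, had -0.44, HMGCS1 -0.30, CYP51A1 0.88 at signals under 87, and SC5D -0.79 on the brightest of probe sets that disagreed. The ribosomal protein list had a median of -0.05 over 54 members, with RPL31 at -0.33, RPS7 at -0.22, RPS16 at -0.21 and RPL22 at -0.20, at the 1.40th percentile. The oxidative phosphorylation list had a median of 0.05 over 43 members at the 99.4th percentile, with COX5A at 0.27, NDUFA10 at 0.25 and NDUFB6 at 0.23, and ATP5J at -0.30 on probe sets that went both ways. With the arrays centred on their medians the oxidative phosphorylation median was -0.0030, against a median of -0.04 over all genes measured. The cholesterol synthesis list was outside the central 95% under 6 of 9 alternative settings, and the ribosomal protein list was inside it after loess on brightness, at the 2.89th percentile. Without _x_at and _s_at probe sets the oxidative phosphorylation list was inside the central 95%, at the 96.4th percentile.

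**Figure D3:**
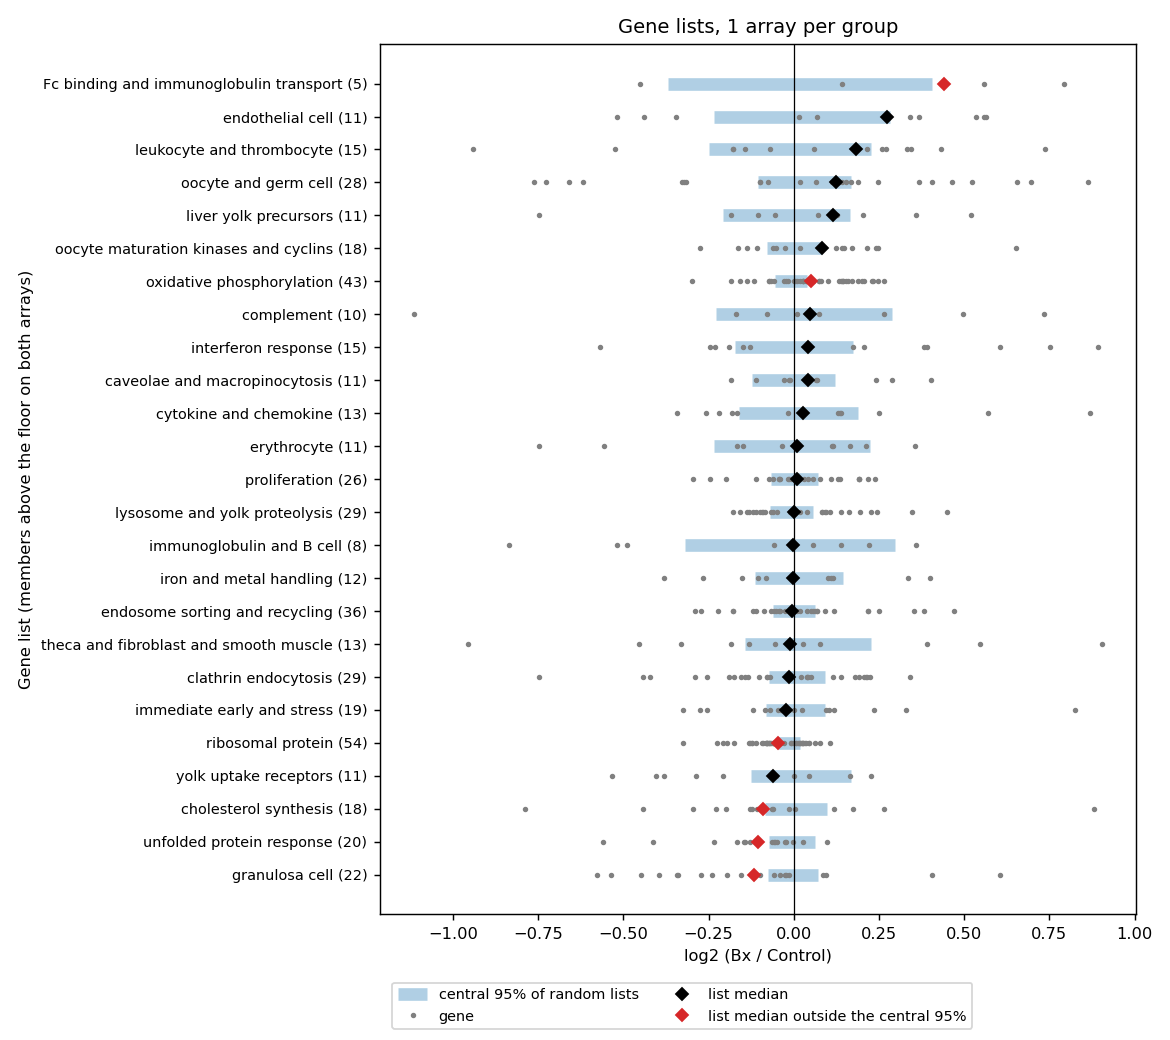
Log2 ratio of the Bx over the control signal for 25 gene lists, with grey points for genes above the floor on both arrays, diamonds for list medians and blue bars for the central 95% of medians of 10000 random lists matched on size and brightness. The 6 red diamonds outside the bars include the granulosa cell list at -0.12 and the unfolded protein response list at -0.11.

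With the arrays centred on their medians every list median was lower by the same amount, so the sign of a positive median of 0.05 or less was not settled. The interferon, complement and cytokine lists had medians inside the central 95% of random lists. The interferon response list had a median log2 ratio of 0.04 over 15 members, with 3 at least 1.5-fold higher and 0 lower. Its direction was not settled: with the stricter floor, which left 5 members, the median was -0.15, at the 4.98th percentile, and with the mean over probe sets it was 0.17, at the 96.6th. MX1, an antiviral GTPase gene, was 1.86-fold higher at signals of 43.4 and 80.5, TAP1 1.68-fold and TAP2, its partner in peptide transport, 1.52-fold, while IFI6 had -0.57. The complement list had a median of 0.05 over 10 members, with C1R 1.66-fold higher, C5 at 0.50, C7 at 0.27 on probe sets that went both ways, and C8G 2.16-fold lower. The cytokine and chemokine list had a median of 0.03 over 13 members, and of -0.09 with no floor, with IL6 1.83-fold higher at signals of 72.0 and 132, LITAF at 0.57, TNFAIP3 at -0.34 and TNFSF10 at -0.26 on probe sets that went both ways. Of the innate and antimicrobial list 2 members were measured in both pools, DEFB4A, an avian beta-defensin gene, 1.88-fold higher, and TF, ovotransferrin, at -0.10 on probe sets that went both ways.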

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

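One value outside the gene comparison stood above its level in the control pool. The non-chicken probe set NC-001958.CDS10.S1_at, designed for a virus sequence, had a signal of 26.9 on the control array, under the floor, and 87.9 on the Bx array. It was the only 1 of 746 non-chicken probe sets that was at least 2-fold higher in the Bx pool and 1 log2 unit over the floor.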

How the results depend on the processing

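No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. Direction counts depended most on what counted as measured. The 65 genes higher and 43 lower became 769 and 740 with no floor, 0 and 2 with the stricter floor (0% higher), 37 and 19 with a pseudocount of 16, 418 and 369 at 1.5-fold, 7 and 6 at 3-fold, and 15 and 15 when at least 2 probe sets had to be past 1.5-fold one way, a count chosen after seeing the data. Median centring gave 66 lower genes and 43.6% higher, with a median log2 ratio of -0.04 over genes. Loess gave 69 higher and 39 lower genes and kept 58 and 33 of the main ones. Quantile normalization gave 57 higher and 52 lower and kept 57 and 43. The 128 one-sided genes (95 higher, 33 lower) became 50 (41 and 9) with the pseudocount, and with the stricter floor 0 in all, 0 higher and 0 lower. The balance of directions among the 128 was not settled, because the main floor was lower on the Bx array. The count of Fc-binding and yolk uptake genes past 1.5-fold (1 higher, 0 lower) became 6 and 2 with no floor. It became 0 higher with the stricter floor, and gained 1 lower with median centring or the mean over probe sets. List medians of log2 ratio that moved by more than the SD of random medians were as follows. With median centring they were -0.069 for clathrin endocytosis, -0.059 for endosome sorting, -0.056 for the lysosome list, -0.17 for granulosa cells, -0.16 for the unfolded protein response, -0.14 for cholesterol synthesis, -0.10 for ribosomal proteins, -0.08 for immediate early genes, -0.046 for proliferation, 0.03 for oocyte maturation and -0.0030 for oxidative phosphorylation, which turned its sign. This setting moved every list by the same amount and no percentile. With the stricter floor they were -0.071 for clathrin endocytosis, -0.17 for granulosa cells and -0.15 for interferon response, with no floor -0.27 for immunoglobulin and B cells, 0.02 for endothelial cells and -0.09 for cytokines, with the mean over probe sets -0.16 for immunoglobulin and B cells, 0.15 for Fc binding, 0.17 for interferon response, -0.066 for ribosomal proteins, 0.050 for proliferation and 0.02 for oocyte maturation, and without _x_at and _s_at probe sets -0.048 for the lysosome list and 0.13 for cytokines. Ribosomal proteins had -0.030 after quantile normalization and -0.022 after loess, and interferon response 0.17 without members whose probe sets disagree. The granulosa list stayed outside the central 95% of random lists in 8 of 9 settings, the unfolded protein response list in 9 of 9, oxidative phosphorylation and ribosomal proteins in 8 of 9, cholesterol synthesis in 6 of 9 and Fc binding in 4 of 7. Of the lists inside it, oocyte maturation was outside in 4 of 9 settings and endothelial cells in 2 of 8. Of 1000 values of named genes under the alternatives, 15 moved by more than 1 SD between probe sets and 0 turned the sign of a gene past 2-fold. Of the 15, 10 came with the mean over probe sets and 5 without _x_at and _s_at probe sets. The SD between probe sets was wider than the SD over genes in all but the dimmest group, so it was a loose limit there. The floor settings cannot change a gene's value, and median centring shifts all genes by the same small amount. Unmoved values under these settings are therefore no sign of robustness. The cause of the shifts between settings was not tested, except that floors and thresholds change which genes enter. Signal over background limits most of the 2-fold genes.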

Other observations

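Further gene groups had medians inside the central 95% of random lists. The proliferation list had a median log2 ratio of 0.0086 over 26 members (58.0th percentile of random lists), with CENPF at -0.30 on probe sets that went both ways, NUF2 at -0.25, MCM3 at 0.24 and NDC80 at 0.22, none past 1.5-fold. Immediate early and stress genes had a median of -0.02 and a mean of 0.02 over 19 members (33.5th percentile), with HMOX1, heme oxygenase, 1.77-fold higher at signals of 62.2 and 110, KLF6 at 0.33, FOS at -0.33 and CCN2 at -0.28. The iron and metal list had a median of -0.0035 and a mean of 0.0055 over 12 members (41.5th percentile), with SLC39A8 at 0.40 on probe sets that went both ways, TFRC at -0.38, MT3 at 0.33 and SLC30A1 at -0.27. Transcripts of the liver's yolk precursor and plasma protein genes had a median of 0.12 over 11 members (92.9th percentile). FGG had -0.75, FGB 0.52, RBP 0.36 and VTG3 0.20 at signals under 162, and VTG1, VTG2 and APOB were not above the floor on both arrays.

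Among 4875 unnamed chicken probe sets above the floor on both arrays, 57 were at least 2-fold higher and 86 at least 2-fold lower in the Bx pool. The lowest ratio among them was that of a probe set with a signal of 360.3 in the control and 37.3 in the Bx pool, and the highest that of one with 44.4 and 195. Among the non-chicken probe sets, AY013303.CDS1.S1_s_at stood far above the floor in both pools, at 4461 in the control and 3051 in the Bx pool (1.46-fold lower).

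Both tests of the granulosa share with their random sets and the test of PLA2R1 were chosen only after the result was seen, as was the use of the number of genes left after loess beside the planned share of genes kept, and the other tests after the overall distribution and the top genes had been seen. The 2-fold genes were weighed first. If they were measurement error of single probe sets, the next probe set of the same gene should show little of the change. Over the 25 genes with one, its log2 ratio, turned to the direction of the first, had a median of 0.13 (bootstrap 95% interval -0.10 to 0.25), and 16 of 25 went the same way, consistent with measurement error for most of them, although the next probe set is dimmer by construction. After loess on brightness there were again 108 genes past 2-fold, 69 higher and 39 lower, and 84.3% of the first 108 were among them (Wilson 95% interval 76.2 to 89.9). The share is under the 90% set beforehand as the bound against brightness-dependent scaling, so the planned test was undecided. The values show only that most of the first 108 stayed past 2-fold once a smooth trend with brightness was removed. A difference between the pools, whether from surgery or from the individual birds, is untested with 1 pool each.

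After loess on brightness the median of the lower granulosa list was -0.11, against -0.12 before. This argues against a smooth trend of the ratio with brightness as its cause. The percentile of the list was still 0.11, but the random lists were matched on brightness, so it could hardly move and decides nothing. A smaller share of granulosa cells in the Bx pool would lower all its markers alike, and the first test of this decided nothing: 0 of 18 bright markers lay further from the list median than 2 SD between probe sets of a gene, but 99.5% of 10000 random lists of as many bright genes passed it too. A second test was made once the first result was known. In it 0.58% of 10000 shuffles of 18 probe sets among 9 markers gave as large a variance between markers. Of 1000 random sets of 9 bright genes, 2.3% gave as low a share of shuffles, and 13.3% gave under 5%. This argues only weakly against a smaller share as the whole cause. Probe sets of 1 marker can share sequence, and an error they share raises the variance between markers too. Values that go with a smaller share are the higher medians of the oocyte (0.12), endothelial (0.27) and leukocyte (0.18) lists. Each was inside the central 95% of random lists, and the erythrocyte (0.0094) and theca (-0.01) lists were close to 0. The endothelial median was 0.02 with no floor, and CD74, the 1 bright leukocyte member, was 1.44-fold lower. The oocyte maturation (0.08) and proliferation (0.0086) lists are not lists of cell type markers. The second test covers 9 of the 22 members, so a smaller share as part or the whole of the cause stays open. Also open is the untested hypothesis of lower INHBA, INHBB and NR5A2 levels within granulosa cells, from bursectomy or from differences between the birds pooled.

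PLA2R1, whose chicken form FcRY binds IgY, was the gene of the Fc-binding list a reader of this screen would look for. Of the 400 genes nearest to it in mean signal, 57 (14.25%) differed between the pools by at least as much in either direction, so its 1.73-fold difference is consistent with the spread of dim probe sets. Its other 2 probe sets were under the floor on both arrays, with signals of 5.95 and 13.4 in the control and 32.7 and 22.9 in the Bx pool, which have no order.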
